A study of Mus musculus with 6 samples.

How the data were processed

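Gene expression was measured on 6 one-colour arrays hybridised with Cy3-labelled cRNA from mouse lymphatic endothelial cells, the cells that line lymphatic vessels. The labels describe a cell line and give 2 groups of 3 samples. One group received phosphate-buffered saline (PBS) and the other 300 μg/ml monosodium urate (MSU), the crystal that forms in gout, both for 24 hours. The groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

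Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7.1.1. The authors deposited 1 table of log2 normalized intensities with a column per array, and the steps between the scanner output and this table are not given in the sources used here. The table holds 56745 rows, of which 56605 carry expression probe IDs and 140 are control rows. The sorted values of the 6 columns are identical, with a largest difference of 0, which is what quantile normalization between arrays leaves. Each column therefore has a lowest value of 1.47, a median of 4.88 and a highest value of 18.2. The log base is not stated and was taken as 2 from this range, and fold changes depend on it. Values were not centred per probe. Scanner signals and detection flags were not used here, so the precision of a value is known only from the spread between arrays, whose number limits it.

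The table names probes by ID alone. None of the rows of the mouse gene table used for names (RefSeq, GRCm38.p6) holds a probe ID, so 0 probes were matched to a gene. The test was planned per gene and was run per probe, as written for this case before the data were examined. A gene can be represented by several probes, so a count of probes is not a count of genes. The 32 gene lists fixed beforehand (endothelial, inflammatory, stress, metabolic and cell type lists) and the individual genes fixed for naming were not tested, and neither were the alternatives that need gene names.

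Probes whose mean over the 6 arrays lay below the 40th percentile of all expression probes, a log2 level of 3.19, were left out as dim. This left 33963 probes. MSU and PBS arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate), two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Calls with a log2 change of at least 1, a 2-fold change, were also counted apart. The naming rule took the 8 probes with the largest rise and the 8 with the largest fall in fitted log2 change among those past the threshold whose MSU and PBS values did not overlap. Because no gene can be given, only the first 2 of each are named.

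As a background limit, chosen after the data were seen, the 95th percentile of all values of the 109 ERCC and ETG control rows was used, a log2 level of 2.56. Taken per array over these rows, the percentile was 3.60 on PBS replicate 1 and between 2.23 and 2.58 on the other arrays. The rows lie mostly at the lower end of the scale. Their role is not stated in the files, so the limit is an assumption. Where all arrays of a group lay at or under the limit, the fold is a lower bound. It compares the mean of the brighter group with the mean, per array, of the higher of the limit and the probe's own value. The 10 E1A rows, read as added spike-in controls from their names, served as a check on scaling.

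The test was tried on simulated values for the 33963 probes of the MSU against PBS comparison, with each probe's own mean and replicate spread and 200 changed probes. It recovered 52% of the probes changed by 1 on the log2 scale and 90% of those changed by 2. It called 4 unchanged probes, and it called 0 probes when none was changed. The simulated noise was independent between probes, so false calls from deviations that many probes of an array share could not appear. The data gave 7319 calls, far more than the 200 changed probes simulated, and the adjustment is stricter when fewer probes change. The recovered shares therefore need not hold for the reported comparison.

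The alternatives set before the data were examined were other filters on dim probes, other scalings, an intensity trend with a robust prior, array weights, the replicate number as a block, a threshold of 0.01 and leaving out each array in turn. Centring on the spike-in rows, centring on the tested probes and a filter on the background limit were added afterwards. Figures were drawn with matplotlib 3.10.9.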

Results

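Expression profiles were collected from mouse lymphatic endothelial cells after 24 hours with PBS, the control, or with 300 μg/ml MSU. Each group held 3 arrays. The series concerns lymphatic vessels in gouty arthritis, and its design asks which transcripts of these cells differ once urate crystals are added. The files used here identify transcripts only by probe ID, so the results below describe probes and groups of probes, without gene names. On each array about 66.1% of the 56605 expression probes lay above the background limit, and the common scale fixes this share to nearly the same value on every array.

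The arrays separated by treatment. Across the 33963 tested probes, the Pearson correlation between 2 arrays of one group was 0.992 to 0.995 for PBS and 0.992 to 0.994 for MSU. Between a PBS and an MSU array it was 0.983 to 0.987, below every within-group value. These are correlations across probes, which are not independent replicates. The first principal component carried 54.9% of the variance. PBS arrays had scores of −50.1, −49.6 and −35.2 on it, and MSU arrays had scores of 48.2, 45.2 and 41.5.

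After MSU, 3707 probes were higher and 3612 were lower than after PBS (limma, Benjamini-Hochberg adjusted p under 0.05), together 21.5% of those tested. At this threshold rises and falls were about equally frequent, and the rises were larger. The median fold was 1.59 among the probes that rose and 1.42 among those that fell. Of the calls, 979 were at least 2-fold higher and 300 at least 2-fold lower, so that 76.5% of the 2-fold calls were rises. For 19 of these rises no PBS array was above the background limit, and for 5 of these falls no MSU array was. By fitted change, 218 probes rose and 24 fell by 4-fold or more, and 64 rose and 3 fell by 8-fold or more. A further 3767 calls, 51.5% of the total, were changes of less than 1.5-fold. Over all tested probes the median log2 change was −0.05. The shared distribution of the columns gives both groups the same mean over all rows, whatever the treatment did. The near balance of rises and falls, and this small median, therefore depend in part on the scaling. The MSU and PBS values did not overlap for 42.1% of the tested probes, where chance gives 10% for 3 arrays against 3, and none of the 7319 called probes had overlapping values. The counts and their balance moved with the setting, to 1789 higher and 1054 lower at an adjusted p under 0.01, 5245 and 5774 with array weights, 2415 and 1659 without PBS replicate 1, 2240 and 1530 without PBS replicate 2, 2178 and 1699 without MSU replicate 2, and 2355 and 1924 without MSU replicate 3. When each array was centred on its spike-in probes, which vary between arrays themselves, 946 probes were higher and 262 lower. That is 78.3% rises against 50.6% before, all of them changes of at least 2-fold, for which the share before was 76.5%. With this centring the adjusted p followed the size of the change and hardly the spread of the probe. Probes A_51_P145511 and A_55_P2810278, with MSU SDs of 0.79 and 0.24 before centring, had adjusted p of 3.58e-16 and 4.21e-16 (limma). The setting thus acted much like a cut on fold, so its share of rises is no separate evidence.

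**Figure D1:**
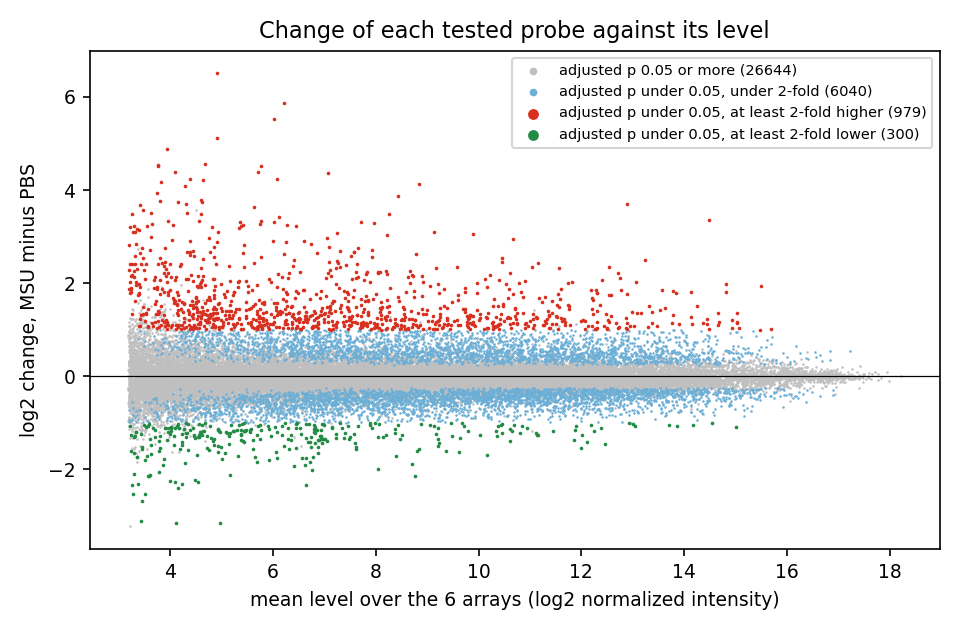
The log2 change of each tested probe (MSU minus PBS, vertical) is plotted against its mean log2 normalized intensity over the 6 arrays (horizontal). Each point is 1 of 33963 probes, coloured by call. The 979 probes at least 2-fold higher reach further from 0 than the 300 at least 2-fold lower, at low and at high levels.

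Bright probes were called more often than dim ones. The share of called probes was 8.24% among those with a mean log2 level under 4 and 16.4% between 4 and 6. It reached 27.8% between 12 and 14, and was 17.8% at 14 and over. The median SD between replicate arrays fell over the same levels, from 0.51 to 0.07 on the log2 scale, so smaller changes could be detected in brighter probes. Rises outnumbered falls among the 2-fold calls at every level. Between 4 and 6 there were 287 rises and 106 falls, and between 12 and 14 there were 63 and 11.

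**Figure D2:**
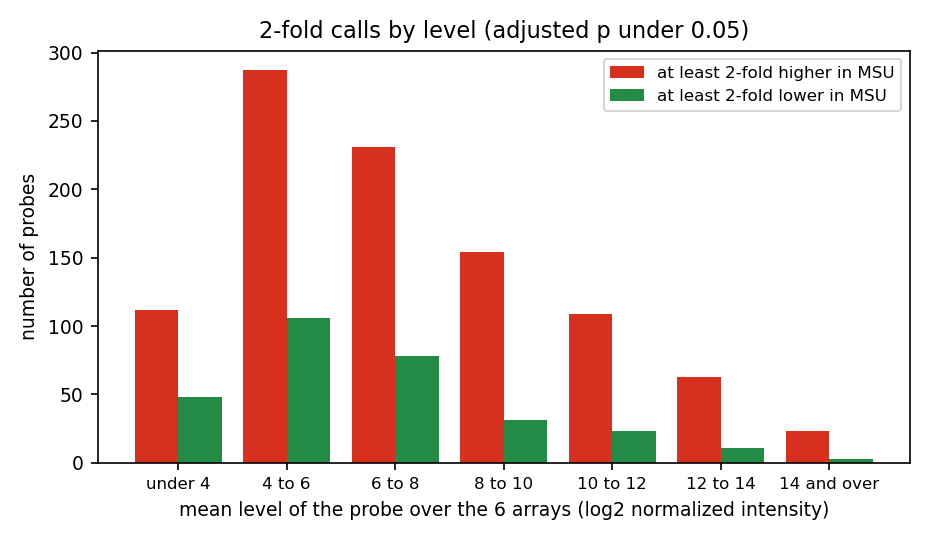
Bars give the number of probes (vertical) called at least 2-fold higher or lower in MSU with an adjusted p under 0.05, by mean log2 normalized intensity of the probe over the 6 arrays (horizontal). Rises exceed falls in each of the 7 level classes, from 112 against 48 in the dimmest to 23 against 3 in the brightest.

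Of the probes that rose, the naming rule picked A_51_P255699 and A_55_P1952628 first. The log2 normalized intensity of A_51_P255699 was 3.28 ± 0.16 (SD, n = 3) with PBS and 9.15 ± 0.14 (SD, n = 3) with MSU, above the background limit on all 6 arrays. Its log2 change was 5.87 with a standard error of 0.12, or 58.3-fold (limma, adjusted p = 6.15e-05). Probe A_55_P1952628 lay at 1.66 ± 0.24 with PBS and at 8.17 ± 0.28 with MSU (SD, n = 3). All PBS arrays lay under the background limit for this probe, so it was at least 48.9-fold higher with MSU (limma, adjusted p = 9.34e-05), and the order of these probes is not known. For 4 of the 8 probes that the rule picked among the rises, no PBS array was above the limit, and these were at least 11.04-fold to at least 48.9-fold higher. Of the other 4, 2 had a PBS mean above it and fitted log2 changes of 5.53 and 5.87, and 2 had a PBS mean under it, so the size of their rises is uncertain.

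Among the falls the rule picked A_51_P145511 and A_55_P2810278 first. Probe A_51_P145511 went from 6.56 ± 0.05 (SD, n = 3) with PBS to 3.39 ± 0.79 (SD, n = 3) with MSU, a log2 change of −3.16 with a standard error of 0.38 (limma, adjusted p = 0.00385). Its MSU values were spread, at 2.56, 3.48 and 4.14, and 2 of them were above the background limit. Probe A_55_P2810278 went from 5.69 ± 0.08 to 2.53 ± 0.24 (SD, n = 3), a fitted log2 change of −3.16 (limma, adjusted p = 0.000216). Its MSU values, 2.74, 2.59 and 2.27, lay on both sides of the limit of 2.56 with their mean under it, so the size of this fall is uncertain. For 3 of the 8 probes picked among the falls no MSU array was above the limit, and these were at least 3.97-fold to at least 5.37-fold lower. Of the other 5, 3 had an MSU mean above it and fitted log2 changes of −2.33 to −3.16, and 2 had an MSU mean under it, so the size of their falls is uncertain.

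**Figure D3:**
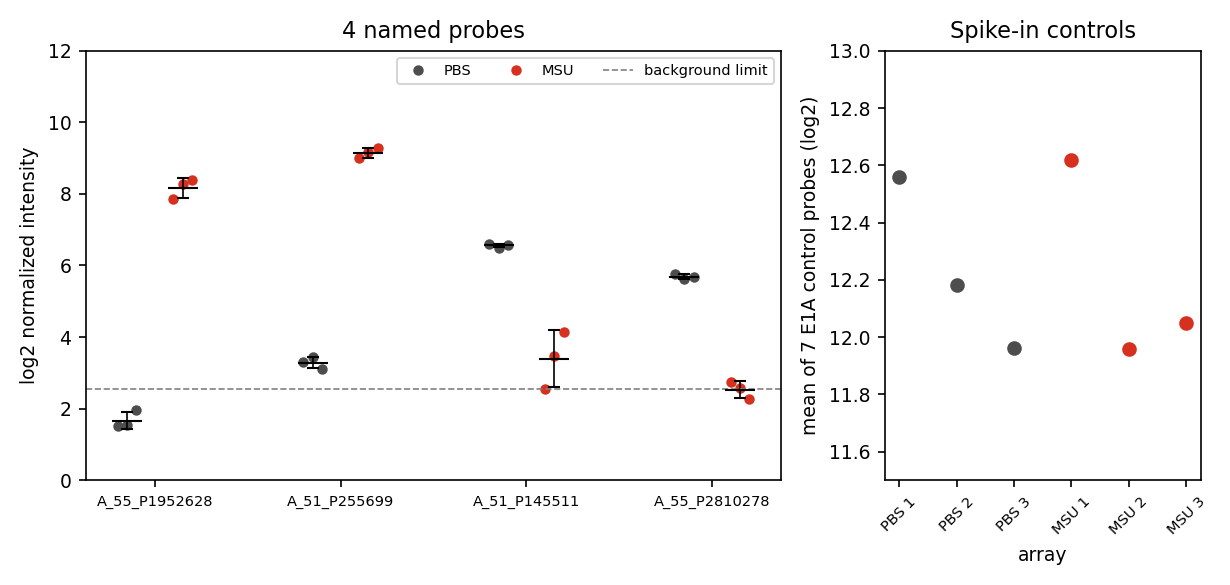
The left panel gives the log2 normalized intensity (vertical) of the 4 named probes on each PBS and MSU array, with horizontal bars for the group mean, error bars for 1 SD and a dashed line for the background limit of 2.56. The right panel gives the mean of 7 E1A spike-in probes on each array (log2 scale, vertical axis not starting at 0), with the first array of each group highest, at 12.6.

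Few probes crossed the background limit in one direction on every array. Of all expression probes, 151 were above it on the 3 MSU arrays and on no PBS array, and 91 on the 3 PBS arrays and on no MSU array. Other divisions of the same 6 arrays into 3 and 3 gave up to 208 such probes one way, so these counts do not stand apart from the spread between arrays. With 1 array left out they ranged from 222 to 337 and from 148 to 250, the highest without PBS replicate 3 and without MSU replicate 3. Leaving out an array removes a condition, so at a fixed limit these counts can only stay or rise.

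Probe IDs fall into 6 series by the prefix before the probe number, and the balance of rises and falls differed between them. In the series A_51_P, 893 probes rose and 689 fell, so that 56.4% of its calls were rises (95% exact binomial interval 54.0% to 58.9%). In the series A_30_P, 163 rose and 212 fell, or 43.5% rises (38.4% to 48.7%), and in the series A_65_P 85 rose and 119 fell, or 41.7% (34.8% to 48.8%). Compared within classes of mean level, the odds that a called probe was a rise were 1.40 times those of the other series for A_51_P (interval 1.25 to 1.57, Mantel-Haenszel test, adjusted p = 2.73e-08 over the 6 series). The odds ratio was 0.68 for A_30_P (0.55 to 0.85, adjusted p = 0.00128) and 0.67 for A_65_P (0.51 to 0.89, adjusted p = 0.0122). The series A_52_P, A_55_P and A_66_P gave odds ratios of 0.90, 0.94 and 1.01, with adjusted p of 0.174, 0.259 and 0.915. Among the 2-fold calls, rises outnumbered falls in each series, from 53 against 32 in A_30_P to 22 against 2 in A_65_P. Several probes of one gene can lie in a series, and all probes were read on the same 6 arrays. Probes are therefore not independent, and these intervals and p-values are too narrow by an unknown amount. The comparison between series was not among the tests set beforehand.

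The control rows were scaled together with the expression probes. The 10 E1A rows spanned mean log2 levels from 1.75 to 17.1, and 7 of them lay at 6 or more. The mean of these 7 was 12.2 ± 0.30 (SD, n = 3) on PBS arrays and 12.2 ± 0.36 (SD, n = 3) on MSU arrays, a difference of −0.03 (exact permutation test, two-sided, p = 0.9, with 0.1 the smallest p that 3 against 3 allows). Their level ranged over 0.66 on the log2 scale between arrays, or 1.58-fold. None of the 140 control rows passed the threshold when adjusted over the control rows alone (limma, smallest adjusted p = 0.201), and 9 had an unadjusted p under 0.05. Adjusted together with all probes, 2 passed, ERCC-00040_174 and ERCC-00044_175, both named after their values were seen. They lay at 1.77 and 1.76 with PBS and at 1.55 and 1.58 with MSU, under the background limit on every array. Over the 109 ERCC and ETG rows, which lie mostly at the lower end of the scale, the median log2 change was −0.06.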

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

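The tests of the balance between rises and falls, and the use of the background limit on dim probes, were chosen after the results were seen. The fit without a filter on dim probes was set beforehand.

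Among the 22642 dim probes left out of the comparison, 241 were called when no probe was left out. Of these, 90 were at least 2-fold higher with MSU and above the background limit on the 3 MSU arrays and on no PBS array, which is why they are listed here. Their median level with MSU was 3.45 and the highest 4.77, above the limit of 2.56 and under the column median of 4.88. The mirror count, at least 2-fold lower and above the limit on the 3 PBS arrays alone, was 36. Over all 56605 probes the fit without a filter called 6482. Of the 140 control rows, 2 passed when adjusted together with all probes.

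The 10 divisions of the arrays into 3 and 3 are too few for a share under 0.05. The real division gave 3707 higher, 3612 lower, 979 at least 2-fold higher and 300 at least 2-fold lower, and in each case 1 of the 10 divisions, the real one, gave as many. The highest count of any other division was 0. Each other division mixes PBS and MSU arrays within a group, so a treatment difference widens its within-group spread and lowers its count.

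The 2-fold calls were unbalanced toward rises, 979 against 300. A floor that shortens the falls of dim probes is argued against as the whole cause, since among probes with a mean log2 level of 8 or more the share of rises was 83.7% (95% exact binomial interval 79.8% to 87.1%). A zero point set too low by the normalization could not be excluded for the 2-fold calls, since lowering every log2 change by 0.22 would balance them and the spike-in difference between the groups, −0.026, has a larger spread within a group, 0.36. That shift is argued against as the whole cause at 4-fold, where it would leave 156 rises and 34 falls, or 82.1% rises (95% exact binomial interval 75.9% to 87.3%). A larger shift of 0.616 would balance the 4-fold calls, at 97 each way. It would leave 356 rises and 2784 falls at 2-fold, and 28 rises and 7 falls at 8-fold. These values argue against 1 shift as the whole cause of the imbalance at both 2-fold and 4-fold. A shift as part of the cause stays open. So does a response of the cells to MSU that raises some transcripts far more than it lowers others, which was not tested.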

How the results depend on the processing

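All 4 named probes kept their direction and stayed past the threshold under every alternative in which they were tested, with adjusted p of at most 0.0211 by limma. Repeating quantile normalization, and setting each array's 75th percentile or median to 0, moved nothing, because the deposited columns already share one distribution. Testing each probe on its own is the comparison as reported. The mean of a gene's probes, the gene list tests and the pseudocounts were not run, as there were no gene names and the values were already logged. No called probe changed sign under the alternatives compared probe by probe. This was mostly fixed beforehand, and so was the direction of the named probes. No called probe had overlapping values, so leaving out or weighting arrays could not turn a sign. Filters, the trend and the block leave the log2 change as it was. Only centring on the spike-in rows or on the tested probes could have turned one. The 2-fold counts were the steadier ones. They changed by over 1.5 times only with probes at or above the 60th percentile, to 516 higher and 126 lower. That filter left 22642 probes and took out the dimmest, which held many of the 2-fold calls. Between log2 levels of 4 and 6 alone there were 287 rises and 106 falls. Without the limit on fold, 1660 were higher and 877 lower with the replicate number as a block, against 3707 and 3612 without it. The labels state no pairing, and the deviations of same-numbered samples from their group means had correlations across probes of −0.10, −0.03 and 0.04, with the highest, 0.19, between PBS replicate 1 and MSU replicate 2, so no pairing was used. With the block the 2-fold counts were 881 and 264. A threshold of 0.01 gave 1789 higher and 1054 lower, array weights gave 5245 higher and 5774 lower, probes at or above the 60th percentile gave 3505 and 4075, the trend with a robust prior gave 4381 and 4707, and centring on the spike-in probes, added after seeing the data, gave 946 higher and 262 lower. Leaving out 1 array at a time gave 2178 to 3529 higher and 1530 to 3278 lower. Of the 7319 calls, 3195 were kept in all 6 of these fits, among them 822 of the 979 2-fold rises and 234 of the 300 2-fold falls. The counts of probes crossing the background limit on all arrays of one group moved by over 1.5 times in 11 of 16 alternatives. Most of these left out 1 array, which at a fixed limit can only keep or raise the counts. Low signal limits what can be read, since the median replicate SD was 0.51 under a log2 level of 4.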

Other observations

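The tests in this part were chosen after the results were seen.

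The third PBS array was displaced from the other PBS arrays in the direction of the MSU arrays. The response was taken as the MSU mean minus 1 PBS array, over probes that differed at least 2-fold, and the other 2 PBS arrays were compared along it. The third PBS array was displaced from the first by 10.3% of the response over 1985 probes, and from the second by 13.4% over 2141 probes. The first and second PBS arrays differed by 3.93%, and MSU arrays, compared in the same way, differed by at most 3.99% in size. The displacement from the second array was 12.01% for rises and 18.3% for falls, and that from the first 11.47% and 6.26%. Among MSU arrays the rises differed by at most 5.30% and the falls by at most 11.3%, which is more than the 6.26%. RNA of MSU-treated cells mixed into that sample would need the same share of MSU signal from every probe. Against the second PBS array, probes 2 to 4-fold higher in MSU needed a median of 8.79% (95% interval 7.36% to 10.3%). Those at least 8-fold higher needed 2.0% (0.79% to 3.47%), a smaller share. Strongly raised probes can lie near the background limit with PBS, as did 4 of the 8 largest rises, so their share is uncertain. Against the first PBS array the shares were 4.51% (3.39% to 5.80%) and 2.24% (0.61% to 3.37%), which barely part, and probes are not independent, so mixing cannot be told apart from another difference of that sample, technical or in the state of the cells, neither of which was tested. Without this array the counts of calls changed from 3707 to 3186 higher and from 3612 to 2657 lower, and they were lower than with all arrays whichever array was left out. The 2-fold counts changed from 979 to 1042 higher and from 300 to 310 lower.

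The spike-in level was highest on the first array of each group, at 12.56 for PBS and 12.62 for MSU, against 11.96 to 12.18 on the other arrays. A candidate explanation is that samples of the same number were labelled together. Of the 6 ways to pair PBS with MSU arrays, 2 gave spike-in deviations at least as similar as those of the same numbers, an exact one-sided p of 0.333 with 0.167 the smallest possible, so this cannot be told apart from chance with 3 pairs.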
